A study of Mus musculus with 16 samples.

How the data were processed

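Hippocampi of 5-month-old mice were measured by RNA sequencing of polyadenylated transcripts in 16 libraries, 4 for each of 4 genotypes. The genotypes were wild-type, Dp16 (a mouse model of Down syndrome with a duplicated segment of chromosome 16), 5xFAD (a mouse carrying human transgenes, APP among them, with familial Alzheimer disease mutations under the neuronal Thy1 promoter) and the cross of both, called 5xFAD-Dp16. Per the labels' protocols, RNA was extracted with TRIzol and made into strand-specific libraries that were read as paired ends. The labels give each library a genotype, a replicate number from 1 to 4 and the sex of the mouse. There were 10 male and 6 female samples: wild-type, Dp16 and 5xFAD had 2 of each sex, and all 4 5xFAD-Dp16 mice were male. The labels do not say outright that each library came from a separate mouse, and p-values measure the spread between these libraries.

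Per the submitters' processing notes, the steps used bcl2fastq, FastQC version 0.11.5, HISAT2 version 2.1.0, SAMtools version 1.5 and HTSeq version 0.6.1 with the mouse build GRCm38. The strand setting used when reads were counted is not given in the sources used here, so reads of overlapping and antisense genes cannot be assigned with certainty. Members of families with near-identical copies are uncertain as well, since a read can match more than 1 copy. Among them are the H2 genes, the Ifit genes, C4b, the clustered protocadherins and the ribosomal proteins with their pseudogenes. The authors deposited a table of raw read counts for 55385 genes and a table of RPKM values (read counts scaled by gene length and library total). In 27505 genes with enough values, the deposited RPKM implied a single gene length across all libraries within a relative tolerance of 1e-06, so the RPKM table was a rescaling of the deposited counts. Total counts ranged from 15.8 to 25 M (mega) per library. The symbols and identifiers were those of the tables. Coordinates came from a GRCm38 reference annotation in which 55144 of the 55385 identifiers were found.

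The counts were analysed with edgeR version 4.0.16 in R version 4.3.3. Genes with too few counts for a test were removed with the default filter of edgeR for the 4 groups, which left 16684 genes. Libraries were scaled with the trimmed mean of M values (TMM). A quasi-likelihood model with robust dispersion had 1 term per genotype and 1 for sex and was fitted over all 16 libraries, which share 1 estimate of the spread. The 5 pairwise comparisons, the interaction (the Dp16 effect with 5xFAD minus the Dp16 effect without it) and the female against male difference were tested in this model. As 5xFAD-Dp16 had no females, its comparisons and the interaction assume that the sex effect of the other genotypes holds in it. A second model over the 3 genotypes with both sexes tested whether the 5xFAD or the Dp16 effect differed between females and males. Genes passed at a Benjamini-Hochberg adjusted p below 0.05. Every log2 fold change is given with a standard error (SE) derived from the fitted value and its test statistic, and library-size-scaled counts (CPM) are TMM-scaled group means ± SD with n = 4.

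Gene lists for cell types, states, pathways and other tissues were fixed before the data were examined. In each comparison 38 lists with at least 3 tested members were tested with camera from limma version 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 38 lists. The same test with a correlation estimated from the residuals was the stricter alternative. The named genes followed a rule that was also fixed before the data were examined. It took 3 genes linked to the transgenes in every genotype comparison, of which App and Thy1 are described. It took up to 8 genes that rose and up to 8 that fell with the largest change among those that passed, reached 1 CPM in the higher group, had no overlap between the groups' CPM, lay outside the triplicated list and had a symbol other than a clone name. Where Dp16 dosage changes, it took the 8 triplicated genes with the smallest p and the receptor genes Ifnar1, Ifnar2, Ifngr2 and Il10rb. It further took up to 4 members with the smallest p of each described list, the 5 genes with the smallest p for differences of effects, and 5 sex-linked genes. Genes named outside this rule are marked as chosen after their values were seen.

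The triplicated segment was taken as the span of chromosome 16 from Lipi to Zbtb21, positions 75540514 to 97962622. Its list held 101 genes, of which 91 were tested. The steps were tested on simulated data with 200 changed genes among the 16684. Genes were drawn independently of each other, with no sex effect and no shared differences in tissue content. In the simulation of Dp16 against wild-type, 31.3% of the genes changed 1.5-fold and 84.8% of those changed 4-fold were recovered, and in that of the interaction 3.03% and 73.8%. The shares were 16.4% and 86.4% for 5xFAD against wild-type. They were 20% and 83.3% for 5xFAD-Dp16 against 5xFAD, and 20.9% and 84.4% for 5xFAD-Dp16 against Dp16. The 24 pairs of libraries within a group all differed by more than sampling noise (chi-square per degree of freedom from 8.34 to 97.49), so none repeated the sequencing of another. Each library was counted, though this does not show that each came from a separate mouse.

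The alternatives were DESeq2 version 1.42.0, another normalization (relative log expression, RLE), no filter on low counts, a stricter filter (at least 1 CPM in 4 libraries), no sex term, males only, a model of only the 2 groups compared, the replicate number as a block, limma on log2(RPKM + 0.1) and on log2(RPKM + 1), and leaving out each library in turn. A list of midbrain and hypothalamus genes and 2 further settings were chosen after seeing the data: leaving out 4 libraries with high levels of those genes, and adding the choroid plexus and midbrain scores of each library as covariates. A score is the mean, over the list's genes, of log2 CPM centred on each gene's mean over the 16 libraries.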

Results

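The data were counts of polyadenylated transcripts in the hippocampus of wild-type, Dp16, 5xFAD and 5xFAD-Dp16 mice at 5 months of age, with 4 libraries per genotype. Mean totals were 22.0 ± 1.34 M counts (M, mega) in wild-type, 20.4 ± 3.04 in Dp16, 17.5 ± 1.37 in 5xFAD and 20.1 ± 3.35 in 5xFAD-Dp16 (SD, n = 4 each). The design asks what the duplicated chromosome 16 segment changes, what the 5xFAD transgenes change, and whether either effect differs in the presence of the other.

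The genes that each genotype targets were examined first. Mouse App, which encodes the amyloid precursor protein and lies in the duplicated segment (GRCm38 chromosome 16, 84949685 to 85173766), was at 2030 ± 236 CPM in wild-type, 3140 ± 95.8 in Dp16, 1830 ± 122 in 5xFAD and 2960 ± 269 in 5xFAD-Dp16 (SD, n = 4). Thy1, the gene whose regulatory sequence drives the 5xFAD transgenes (chromosome 9, 44043384 to 44048579), was at 814 ± 70.2 CPM in wild-type, 858 ± 65.2 in Dp16, 2130 ± 363 in 5xFAD and 2370 ± 536 in 5xFAD-Dp16. Counts assigned to the mouse genes do not measure the human transgenes separately.

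In Dp16 against wild-type, genes of the duplicated segment rose together. Ifnar1, a subunit of the type I interferon receptor, rose 1.65-fold (log2 0.72 ± 0.0767 SE, edgeR adjusted p = 0.00143), from 35.1 ± 1.33 to 57.8 ± 3.68 CPM. Dyrk1a, a kinase gene studied in Down syndrome, rose 1.54-fold (adjusted p = 0.00715), Rcan1, a regulator of calcineurin, rose 1.49-fold (adjusted p = 0.00391), and App rose 1.55-fold (adjusted p = 0.0327). Ifngr2, of the interferon gamma receptor, rose 1.55-fold (adjusted p = 0.0201), while Ifnar2 (1.51-fold, adjusted p = 0.0681) and Il10rb (1.43-fold, adjusted p = 0.99) did not pass over all genes. Brwd1 (1.54-fold), Gart (1.44-fold), Dnajc28 (1.58-fold) and Ltn1 (1.61-fold) also passed in edgeR. When each of the 16 libraries was left out in turn, Ifnar1 and Rcan1 passed each time. The call of App ended without 12 of the libraries (adjusted p up to 0.182), and those of Dyrk1a, Ifngr2, Brwd1, Gart, Dnajc28 and Ltn1 each ended without 2 to 6 libraries among wild-type replicates 1, 2 and 4 and the Dp16 replicates (adjusted p up to 0.13).

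In all, 14 of 16684 genes passed edgeR's test in Dp16 against wild-type, and all 14 were higher. Of these, 13 lay in the segment, and 63 of its 91 tested genes passed when adjusted over the list alone, all upward. The median over the 91 genes was log2 0.521 (1.43-fold), and 84 of the 91 had a positive sign. Per library, the median log2 value of the segment relative to the wild-type mean was 0.562 ± 0.0403 in Dp16 and 0.0151 ± 0.0855 in wild-type (SD, n = 4). The 371 tested genes elsewhere on chromosome 16 had a median of -0.00582, and none passed. The 43 tested human chromosome 21 orthologues on mouse chromosomes 10 and 17 had a median of -0.0475; in edgeR none passed over all genes, and 1 fell when adjusted over the list alone. Cbs, chosen here after its values were seen, passed over all genes with DESeq2 (log2 -0.72, adjusted p = 0.0013), with no low-count filter (adjusted p = 0.000348), without the 4 libraries high in midbrain genes (adjusted p = 0.0117) and without Dp16 replicate 1 (adjusted p = 0.0489), in a range from 0.000348 to 0.576 over the settings run. At an unadjusted p below 0.05 there were 552 genes, against 834 expected with no effect.

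**Figure D1:**
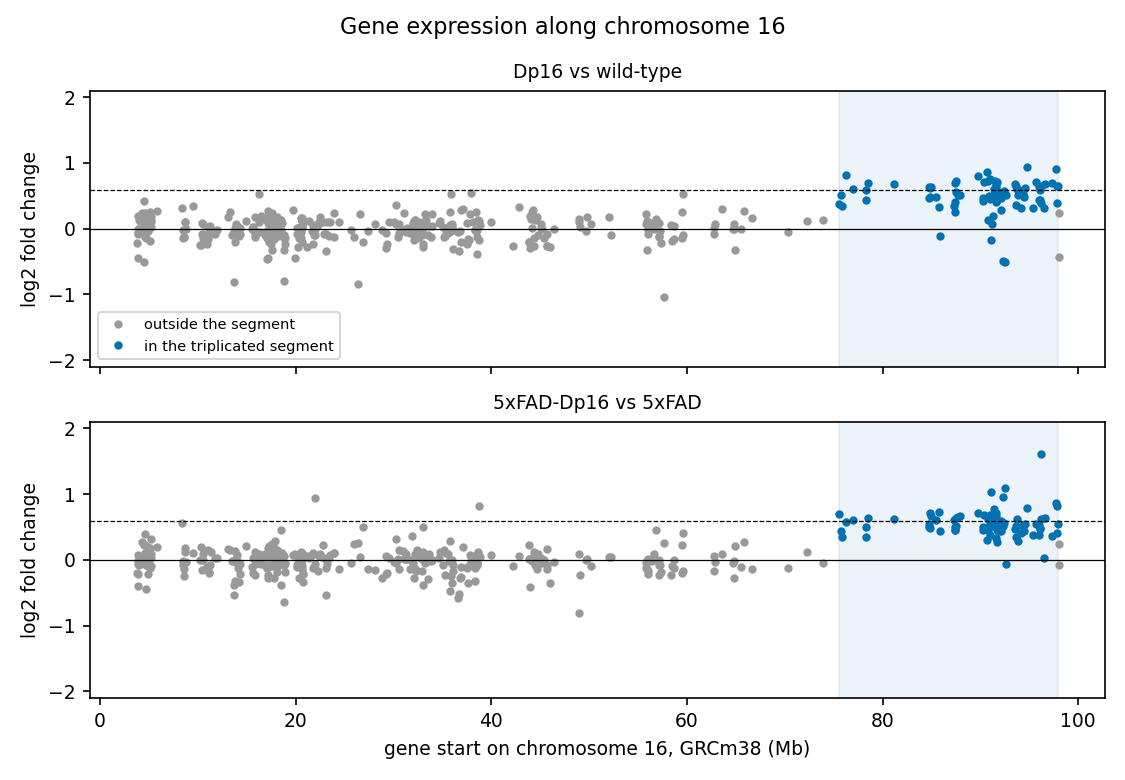
Log2 fold change of each gene with a mean of at least 1 CPM along chromosome 16 (start position in Mb, GRCm38) in Dp16 against wild-type (top) and 5xFAD-Dp16 against 5xFAD (bottom). Blue points are the listed genes of the triplicated segment (shaded), grey points all others, the dashed line marks 1.5-fold, and values beyond 2 or -2 are drawn at that limit. The segment's medians are 0.521 and 0.537.

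The gene that passed outside the segment was a (nonagouti, chromosome 2, 154791402 to 155051012), which encodes the agouti signalling protein of the hair follicle. It had 30 to 57 counts in each of the 8 libraries with the duplication, 0 counts in the 4 wild-type libraries and 3 counts in 1 of the 8 libraries without it. The mean in Dp16 was 2.08 CPM, at least 61-fold higher than the level that 3 counts over the wild-type group would give. Counting intervals and floors of this kind cover counting error only.

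Among the gene lists in Dp16 against wild-type, 16 of 38 passed with the preset correlation and 0 with an estimated one. The interferon response list had a positive sign in 32 of its 39 genes (median log2 0.142, adjusted p = 0.000732, and adjusted p = 0.719 with an estimated correlation), with 0 members passing alone. Dp16 replicate 4 scored 0.0124 against -0.407 to -0.376 in the other Dp16 libraries, and without it the list was not called (adjusted p = 0.0605). Its member with the smallest p was Slfn2 (log2 1.01 ± 0.303, adjusted p = 0.907). Homeostatic microglia genes had a negative sign in 14 of 16 (median log2 -0.163, adjusted p = 0.00313, and adjusted p = 0.719 with an estimated correlation), among them P2ry13 (log2 -0.42 ± 0.174) and Trem2 (log2 -0.34 ± 0.156), and the list was not called without wild-type replicate 1 or 3 or Dp16 replicate 4 (adjusted p = 0.0597, 0.0637 and 0.0605). Activity-dependent genes such as Fos (log2 -0.87 ± 0.25) and Btg2 (log2 -0.95 ± 0.262) were lower in 14 of 20 (adjusted p = 0.0142, and adjusted p = 0.719 with an estimated correlation), and 2 of the 20 fell when adjusted over the list alone. This rested on wild-type replicate 1, whose score was 0.75 against -0.265 to 0.168 in the other wild-type libraries: without it 12 of 20 were higher (median 0.0426, adjusted p = 0.789). The list was not called without wild-type replicate 2 or Dp16 replicate 4 either (adjusted p = 0.0506 and 0.0666), and without wild-type replicate 4 its median was -0.409 (adjusted p = 7.21e-07). Excitatory neuron genes were higher in 12 of 12 (adjusted p = 0.00213, and adjusted p = 0.719 with an estimated correlation). The midbrain and hypothalamus score, which was 3.00 in wild-type replicate 4, lay between -1.32 and -0.595 in the 4 Dp16 libraries, and the excitatory neuron list was not called without that replicate (adjusted p = 0.697), without the 4 libraries high in that score (adjusted p = 0.442) or with the tissue scores as covariates (adjusted p = 0.596). Without wild-type replicate 1 or 2 its median went from 0.198 to 0.313 and 0.311. The count of 14 genes fell to between 3 and 9 when wild-type replicate 1, 2 or 3, any Dp16 replicate, or 5xFAD-Dp16 replicate 1 or 4 was left out. It was 38 with DESeq2 (33 higher and 5 lower, 29 in the segment), 210 with no low-count filter (53 higher and 157 lower), 39 without the 4 libraries high in midbrain genes, and 0 by edgeR in males only, where 400 genes had an unadjusted p below 0.05.

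In 5xFAD against wild-type, the largest changes were rises of microglial genes. Cst7, which encodes cystatin F, rose from 0.158 ± 0.116 to 44.5 ± 16.3 CPM (log2 8.05 ± 0.442 SE, edgeR adjusted p = 1.16e-07). Clec7a, the beta-glucan receptor dectin-1, rose 51.3-fold, Itgax, the integrin CD11c, rose 43.8-fold, and Ccl3, a chemokine, rose 26.2-fold. Trem2, a lipid-sensing receptor of microglia, rose from 10.4 ± 1.52 to 56.0 ± 12.4 CPM (log2 2.43 ± 0.155) and its adaptor Tyrobp from 11.1 ± 1.65 to 55.6 ± 10.9 CPM (log2 2.33 ± 0.134). Ctse, a cathepsin, Pdcd1, the PD-1 receptor, Ly9 and Cd22, both immune cell surface receptors, completed the 8 largest rises that the rule named.

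edgeR called 162 of 16684 genes in 5xFAD against wild-type, of which 161 rose. The exception was Frem3, an extracellular matrix gene, which fell (log2 -1.60 ± 0.325, adjusted p = 0.0227). Its level was 2.58 ± 1.22 CPM in wild-type and 0.826 ± 0.224 in 5xFAD, with 4.39 CPM in wild-type replicate 4 and at most 2.18 in the other wild-type libraries. This call ended without wild-type replicate 3 or 4 or 5xFAD replicate 1, 2 or 3 (adjusted p up to 0.0988). It also ended in males only, with either limma setting, without the 4 libraries high in midbrain genes and in a model of the 2 groups (adjusted p from 0.103 to 0.247). Thy1 rose 2.63-fold (log2 1.39 ± 0.158, adjusted p = 0.000101). App (log2 -0.15 ± 0.105, adjusted p = 0.689) did not pass. The segment's median was 0.0407, and the 2 of its genes that passed were, chosen here after their values were seen, Samsn1 (log2 2.12, adjusted p = 8.51e-06) and Runx1 (log2 1.65, adjusted p = 0.00274), both expressed in blood-lineage cells.

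Lists of microglial and immune genes moved upward together in 5xFAD. Of 29 tested genes of disease-associated microglia, a state described around amyloid plaques, 16 rose over all genes and 21 passed when adjusted over the list alone (median log2 1.32, adjusted p = 4.58e-05 with an estimated correlation). Of 31 lysosomal genes 14 rose, and 20 passed when adjusted over the list alone (adjusted p = 4.77e-05 with an estimated correlation), with the proteases Ctss (log2 1.60 ± 0.109) and Ctsd (log2 1.32 ± 0.108) among them. Of 15 complement genes 6 rose, and 9 passed when adjusted over the list alone (adjusted p = 0.00319 with an estimated correlation), including C1qa, C1qb and C1qc, the subunits of the initiating complex, at 2.83-, 2.71- and 2.72-fold. Of 17 antigen presentation genes 5 rose, and 10 passed when adjusted over the list alone (adjusted p = 0.014 with an estimated correlation), among them B2m (log2 1.05 ± 0.101) and H2-D1 (log2 1.02 ± 0.124). All 39 interferon response genes had a positive sign (median log2 0.703, adjusted p = 0.014 with an estimated correlation). Of these 4 rose over all genes, namely Lgals3bp, Trim30a, Ifit3b and Slfn2, and 29 passed when adjusted over the list alone. Each of these 4 calls ended without 4 or 5 single libraries, among them wild-type replicate 1 (adjusted p up to 0.122).

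The homeostatic microglia list, named for genes of resting microglia, also moved upward (median log2 0.724, adjusted p = 0.0237 with an estimated correlation). Of its 16 genes 8 rose, and 14 passed when adjusted over the list alone. Trem2, Gpr34 (log2 1.49 ± 0.173), a lysophospholipid receptor, and Siglech (log2 0.90 ± 0.126), a sialic acid-binding lectin, were among the 4 with the smallest p. Chosen after their values were seen, P2ry12 (log2 0.57 ± 0.129, adjusted p = 0.0474) and Cx3cr1 (log2 0.62 ± 0.14, adjusted p = 0.0469) rose, and Tmem119 (log2 0.20 ± 0.13, adjusted p = 0.674) did not pass. In the reactive astrocyte list 5 of 25 genes rose and 9 passed when adjusted over the list alone, but the list itself was not called with the stricter test (adjusted p = 0.0843 with an estimated correlation). Among its members Gfap, the astrocyte intermediate filament, rose from 433 ± 35.4 to 1180 ± 279 CPM, and Cd14, Aspg and C4b also rose. Cd14 is a receptor of myeloid cells as well.

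**Figure D2:**
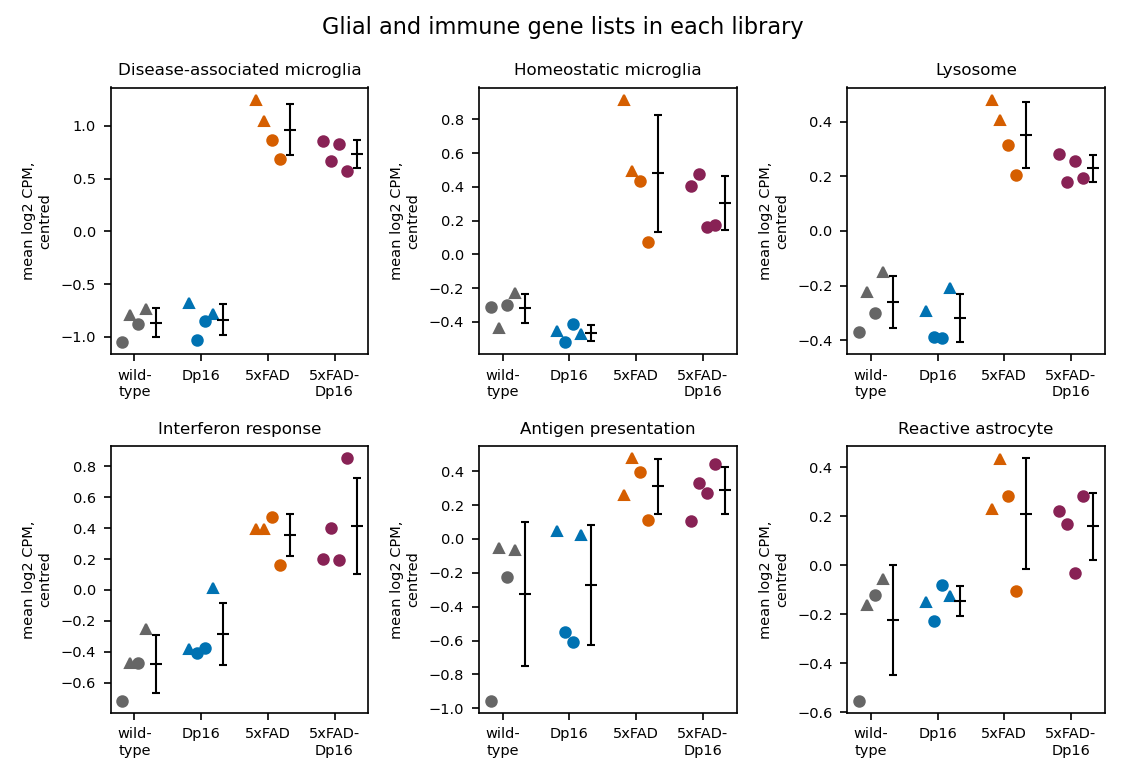
Score of 6 gene lists (mean centred log2 CPM over the list's genes) in each library, by genotype, with circles for males and triangles for females; black bars are the mean and SD of the 4 libraries. Disease-associated microglia scores averaged -0.864 in wild-type, -0.834 in Dp16, 0.965 in 5xFAD and 0.733 in 5xFAD-Dp16.

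Neuronal lists lay in the other direction in 5xFAD, with no member of the interneuron, presynaptic and postsynaptic lists passing over all genes in edgeR. Interneuron genes had a negative sign in 18 of 22 (median log2 -0.185, adjusted p = 0.000301, and adjusted p = 0.108 with an estimated correlation), with Sst, the somatostatin gene, at log2 -0.46 ± 0.128 (adjusted p = 0.157). Sst passed with DESeq2 (log2 -0.47, adjusted p = 0.0314) and with no low-count filter (adjusted p = 0.0339), in a range from 0.0314 to 0.71 over the settings run. With no low-count filter Lhx6 (log2 -0.68) and, upward, Pvalb (log2 0.45), named after their values were seen, passed as well. Without wild-type replicate 4 the interneuron median was -0.121 (adjusted p = 0.0474). Presynaptic genes had a median of -0.177 (adjusted p = 0.000365, and adjusted p = 0.612 with an estimated correlation) and postsynaptic genes one of -0.218 (adjusted p = 0.000215, and adjusted p = 0.621 with an estimated correlation). Oligodendrocyte genes were higher in 18 of 18 (median log2 0.299, adjusted p = 1.4e-05, and adjusted p = 0.531 with an estimated correlation). Ribosomal protein genes were higher in 50 of 50 (median log2 0.267, adjusted p = 1.13e-09, and adjusted p = 0.618 with an estimated correlation). The ribosomal protein score was 0.733 in 5xFAD replicate 4 and 0.00917 to 0.117 in the other 5xFAD libraries, and without that replicate the median fell to 0.0508 (adjusted p = 0.0789). Markers of neighbouring brain regions moved with these lists: thalamus genes were higher in 12 of 12 (median log2 0.975, adjusted p = 0.00181, and adjusted p = 0.532 with an estimated correlation). The midbrain and hypothalamus score was 4.07 in 5xFAD replicate 2, 2.02 in 5xFAD replicate 4, 3.00 in wild-type replicate 4 and 3.12 in 5xFAD-Dp16 replicate 3, and at most -0.403 in the other libraries. The same 4 libraries had the lowest CA1 scores, from -1.02 to -0.487, and the lowest postsynaptic scores, from -0.561 to -0.37. With the tissue scores as covariates the presynaptic (adjusted p = 0.0951) and postsynaptic (adjusted p = 0.0555) lists were not called, and without those 4 libraries they were called (adjusted p = 0.000188 and 0.00046) while the thalamus list was not (adjusted p = 0.568). Without 5xFAD replicate 4 alone the presynaptic (median -0.0537, adjusted p = 0.193), postsynaptic (median -0.0724, adjusted p = 0.135) and thalamus (median 0.245, adjusted p = 0.545) lists were not called. The presynaptic median was -0.279 without wild-type replicate 4 and -0.117 without wild-type replicate 1 (adjusted p = 0.0494), and the postsynaptic one -0.399 without wild-type replicate 4 and -0.396 without 5xFAD replicate 1.

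**Figure D3:**
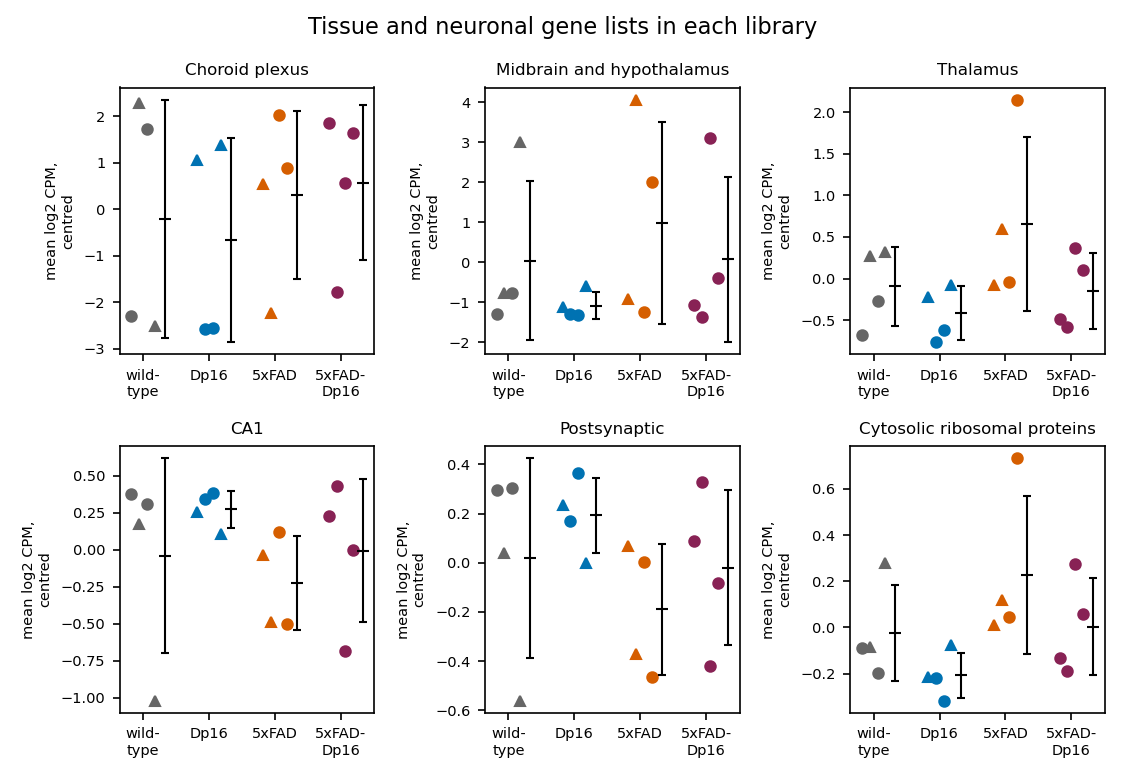
Score of 6 tissue and neuronal gene lists (mean centred log2 CPM over the list's genes) in each library, by genotype, with circles for males and triangles for females; black bars are the mean and SD of the 4 libraries. Midbrain and hypothalamus scores of 2.02 to 4.07 mark 4 libraries, and choroid plexus scores between -2.57 and -1.78 mark 6.

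The count of 162 genes was 292 with DESeq2 (26 lower), 398 with no low-count filter (70 lower), 44 in males only and 76 in a model of the 2 groups alone. At an unadjusted p below 0.05 there were 1477 genes, against 834 expected with no effect.

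In 5xFAD-Dp16 against wild-type, the microglial rise and the rise of the duplicated segment were both present. Cst7 rose by log2 7.61 ± 0.474, Itgax by 5.37 ± 0.472, Clec7a by 5.29 ± 0.386 and Ccl3 by 5.00 ± 0.633 (edgeR adjusted p at most 0.000374). Hcar2, a hydroxycarboxylic acid receptor, was at 0 counts in wild-type and 1.05 ± 0.597 CPM in 5xFAD-Dp16 (adjusted p = 0.00849). Samsn1, a triplicated gene of blood-lineage cells, rose 5.53-fold, from 1.17 ± 0.166 to 6.23 ± 0.553 CPM. Against wild-type, it was at log2 2.12 in 5xFAD and 0.348 in Dp16 (edgeR adjusted p = 8.51e-06 and 0.99). All 4 receptor genes of the segment rose: Ifnar2 1.92-fold, Il10rb 2.02-fold, Ifngr2 1.60-fold and Ifnar1 1.56-fold. App rose 1.42-fold (adjusted p = 0.0425) and Thy1 rose 2.84-fold. The call of App ended without 14 of the 16 libraries left out in turn (adjusted p up to 0.141), and that of Il10rb without wild-type replicate 1 (adjusted p = 0.0718).

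edgeR called 169 genes in this comparison, 164 higher and 5 lower, of which 26 lay in the segment. The median of the segment was log2 0.576 (1.49-fold), 91 of 91 genes had a positive sign and 66 rose when adjusted over the list alone. The named genes that fell were Cbs (log2 -0.67 ± 0.15, adjusted p = 0.0463), which encodes cystathionine beta-synthase and is a human chromosome 21 orthologue lying on mouse chromosome 17, Pik3r3 (log2 -0.52 ± 0.103, adjusted p = 0.0185), a regulatory subunit of phosphoinositide 3-kinase, and Kcnk2 (log2 -0.42 ± 0.0936, adjusted p = 0.0442), a potassium channel; the other genes that fell were the unnamed clones Gm17322 and Gm49980. The call of Cbs ended without 12 of the 16 libraries left out in turn (adjusted p up to 0.313), that of Kcnk2 without 13 (up to 0.296) and that of Pik3r3 without wild-type replicate 3 or 5xFAD-Dp16 replicate 1 or 2 (up to 0.0871). The interferon response list had 10 genes that rose over all genes and 32 that passed when adjusted over the list alone (median log2 0.884, adjusted p = 0.00307 with an estimated correlation). Among them were Irf7, a transcription factor of the interferon response (log2 1.85 ± 0.328), and Oasl2 (log2 1.64 ± 0.305), whose calls ended without wild-type replicate 1 (adjusted p = 0.0718 and 0.0942), and that of Irf7 also without wild-type replicate 3. Disease-associated microglia (17 of 29 rose), lysosome (12 of 31), complement (7 of 15), antigen presentation (5 of 17), homeostatic microglia (4 of 16) and reactive astrocyte genes (5 of 25) were called with either correlation. Adjusted over the list alone, 19, 19, 9, 12, 12 and 7 of them passed. The count of 169 was 80 without wild-type replicate 1, 99 without wild-type replicate 3, 267 with DESeq2, 61 in males only and 40 in a model of the 2 groups alone.

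In 5xFAD-Dp16 against 5xFAD, the question was what the duplication changes where amyloid transgenes are present. As all 5xFAD-Dp16 mice were male, the answer assumes that the sex effect of the other genotypes holds in them. Genes of the segment rose: Ifngr2 1.65-fold (log2 0.72 ± 0.106, adjusted p = 0.0227), Ifnar1 1.51-fold and Rcan1 1.48-fold (adjusted p = 0.0195 each), and Dyrk1a 1.46-fold (adjusted p = 0.0405). Gart, Gabpa, Dnajc28 and C2cd2 also rose, by 1.45- to 1.75-fold. Each of these calls ended without at least 7 of the 16 libraries left out in turn (adjusted p up to 0.277). App (1.58-fold, adjusted p = 0.0574), Ifnar2 (1.58-fold, adjusted p = 0.0627) and Il10rb (log2 0.77 ± 0.179, adjusted p = 0.377) did not pass over all genes.

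edgeR called 9 genes, all higher: 8 in the segment and a, with 547 genes at an unadjusted p below 0.05 against 834 expected. Of the 91 segment genes 90 had a positive sign (median log2 0.537, 1.45-fold), and 60 rose when adjusted over the list alone. The 371 tested genes elsewhere on chromosome 16 had a median of -0.00794. Microglial genes did not pass, although Trem2 was at 37.6 ± 5.24 CPM in 5xFAD-Dp16 and 56.0 ± 12.4 in 5xFAD (log2 -0.48 ± 0.159, adjusted p = 1), and Tyrobp at 37.2 ± 4.75 and 55.6 ± 10.9 (log2 -0.47 ± 0.136, adjusted p = 0.91). Gpr34 (log2 -0.69 ± 0.182) was in the same direction, and 3 of 16 homeostatic microglia genes passed when adjusted over the list alone. The homeostatic microglia list was not called (adjusted p = 0.112), but was called lower without 5xFAD replicate 4 (adjusted p = 3.82e-08) or 5xFAD-Dp16 replicate 1 or 2 (adjusted p = 0.0182 and 0.00792). The disease-associated microglia list (adjusted p = 0.0815) was called lower without 5xFAD replicate 2 or 4 or 5xFAD-Dp16 replicate 1 (adjusted p = 0.0431, 0.00341 and 0.0122). These list calls used the preset correlation, and with an estimated one 0 lists passed in this comparison over all libraries. The 5xFAD group has 2 females, whose disease-associated microglia scores were 1.25 and 1.05 against 0.867 and 0.691 in its males, and all 4 5xFAD-Dp16 mice were male, with scores from 0.577 to 0.86. Homeostatic microglia scores were 0.917 and 0.493 in those females, 0.433 and 0.0762 in those males and 0.161 to 0.476 in 5xFAD-Dp16. The lowest, 5xFAD replicate 4, is male, so leaving it out raised the group's share of females. The 5xFAD effect on this list was larger in females (median log2 0.581, camera adjusted p = 0.000342, and 0.655 with an estimated correlation). Sex and the duplication thus cannot be told apart for these list calls.

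Antigen presentation genes were higher in 14 of 17 (median log2 0.146, adjusted p = 0.0207) and interferon response genes in 29 of 39 (median log2 0.115, adjusted p = 0.0222). With an estimated correlation neither list was called (adjusted p = 0.97 with an estimated correlation for each). Neither was called without wild-type replicate 1 or 4, 5xFAD replicate 1 or 4, or 5xFAD-Dp16 replicate 4 (adjusted p from 0.0563 to 0.924), where without the last the interferon response median was -0.0207. Antigen presentation was not called without 5xFAD-Dp16 replicate 2 (adjusted p = 0.0686), nor interferon response without Dp16 replicate 4 (adjusted p = 0.0728). Other libraries left out raised the medians: without 5xFAD replicate 3 they were 0.342 (adjusted p = 0.000173) and 0.289 (adjusted p = 0.000428), and the interferon response one was 0.222 without 5xFAD-Dp16 replicate 1 (adjusted p = 0.000446) and 0.203 without 5xFAD-Dp16 replicate 3 (adjusted p = 0.00174). Ribosomal protein genes were lower in 50 of 50 (median log2 -0.242, adjusted p = 1.21e-11, and adjusted p = 0.97 with an estimated correlation), as were thalamus genes in 12 of 12 (median log2 -0.849, adjusted p = 0.000134, and adjusted p = 0.97 with an estimated correlation). Ribosomal protein and thalamus scores were highest in 5xFAD replicate 4, at 0.733 and 2.15, and without that replicate the medians were 0.0472 and 0.0386 (adjusted p = 0.242 and 0.736). The count of 9 genes was 27 with DESeq2 (3 lower), 75 with no low-count filter (24 lower), and 0 by edgeR in males only, where 1236 genes had an unadjusted p below 0.05. It was also 0 by edgeR without Dp16 replicate 1, 2 or 3, 5xFAD-Dp16 replicate 1, 2 or 4, or 5xFAD replicate 3, where 452 to 805 genes had an unadjusted p below 0.05, and 3 to 5 without wild-type replicate 1 or 2 or 5xFAD replicate 1 or 4.

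In 5xFAD-Dp16 against Dp16, the effect of the transgenes on the duplicated background was again led by microglial genes. Cst7 (log2 7.58 ± 0.484), Itgax (5.62 ± 0.484), Clec7a (5.24 ± 0.397) and Ccl3 (4.53 ± 0.62) rose most among the named genes (edgeR adjusted p at most 0.000858). Gpr84, a receptor for medium-chain fatty acids, rose 13.2-fold, the chemokine Ccl6 rose 9.15-fold, and St14, a membrane serine protease, rose 8.71-fold. Trem2 rose from 8.15 ± 1.00 to 37.6 ± 5.24 CPM and Thy1 rose 2.70-fold (adjusted p = 0.000205). Banp (log2 -0.79 ± 0.175), Rbm12 (log2 -0.68 ± 0.147) and Klf15, a transcription factor regulated by glucocorticoids (log2 -0.57 ± 0.113), fell. The calls of Banp and Rbm12 each ended without 11 of the 16 libraries left out in turn (adjusted p up to 0.186 and 0.255), and that of Klf15 without Dp16 replicate 2 or 3 or 5xFAD-Dp16 replicate 1, 2 or 4 (up to 0.153).

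edgeR called 141 genes, 138 higher and 3 lower. Disease-associated microglia (15 of 29 rose, 22 adjusted over the list alone), lysosome (13 of 31 and 22), homeostatic microglia (8 of 16 and 16), complement (5 of 15 and 9), antigen presentation (3 of 17 and 10) and interferon response genes (4 of 39 and 27) were called with either correlation. Their adjusted p was at most 0.0254 with an estimated correlation. Oligodendrocyte genes were higher in 18 of 18 (adjusted p = 6.57e-08, and adjusted p = 0.296 with an estimated correlation) and presynaptic genes lower in 23 of 23 (adjusted p = 7.47e-06, and adjusted p = 0.474 with an estimated correlation). 5xFAD-Dp16 replicate 3, with a midbrain and hypothalamus score of 3.12, had an oligodendrocyte score of 0.547 against -0.0845 to 0.0347 in the other 5xFAD-Dp16 libraries. Without it the oligodendrocyte median went from 0.363 to 0.209 (adjusted p = 1.03e-05) and the presynaptic one from -0.19 to -0.126 (adjusted p = 0.000526), and with the tissue scores as covariates the presynaptic list was not called (adjusted p = 0.877). Choroid plexus genes were higher in 16 of 16 (median log2 1.27, adjusted p = 0.0116, and adjusted p = 0.678 with an estimated correlation), with scores of -2.57 and -2.56 in Dp16 replicates 2 and 3 and -1.78 in 5xFAD-Dp16 replicate 2. That list was not called without Dp16 replicate 2 or 3 or 5xFAD-Dp16 replicate 1 or 4 (adjusted p = 0.328, 0.315, 0.14 and 0.0845), and its median was 0.436 without wild-type replicate 2 (adjusted p = 0.0468) and 2.15 without wild-type replicate 3 (adjusted p = 0.00105). The count of 141 was 76 without Dp16 replicate 2, 80 without Dp16 replicate 3, 269 with DESeq2 (19 lower), 620 with no low-count filter (75 lower) and 49 in males only.

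The 5xFAD effects on the 2 backgrounds, from comparisons whose groups share no library, went the same way. Both came from 1 fit with a shared sex term and estimate of the spread, so they are not fully independent. Of 203 genes that passed in either, 201 had the same sign, and 100 rose in both, against 1.33 expected from independent lists. Across those genes, which are not independent replicates, Pearson's r was 0.835 and the slope 0.877; over all 16684 genes r was 0.527. For Dp16, 8 genes rose on both backgrounds against 0.00755 expected, 15 of 15 genes that passed in either had the same sign, and only a lay outside the segment. Over all 16684 genes the r of the Dp16 effects was 0.105.

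**Figure D4:**
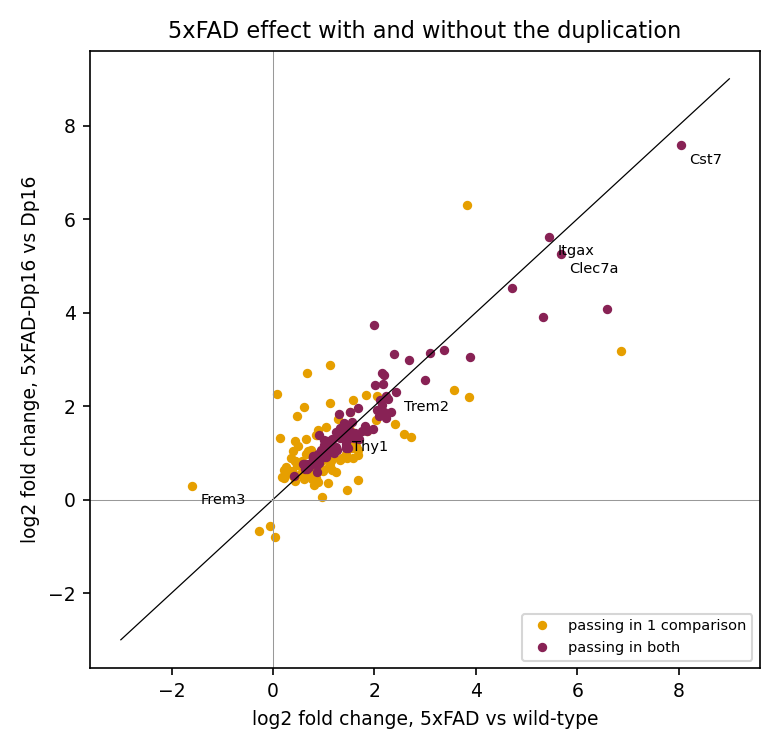
Log2 fold change in 5xFAD against wild-type (horizontal) and in 5xFAD-Dp16 against Dp16 (vertical) for genes that passed in either comparison, with the line of equal effects. Purple points passed in both and orange points in 1; 201 of the 203 genes have the same sign.

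The interaction asks whether the Dp16 effect differs with and without 5xFAD. It also assumes that the sex effect of the other genotypes holds in the all-male 5xFAD-Dp16 group. edgeR called 0 genes, with 332 at an unadjusted p below 0.05 against 834 expected, and DESeq2 called 0. With no low-count filter, where 30883 genes were tested, many with very few counts, edgeR called 128, of which 115 were positive. The smallest p belonged to Cfap100 (log2 -1.39 ± 0.316), Rbm41 (log2 -1.15 ± 0.271), Frem3 (log2 1.90 ± 0.458), Rhbdl2 (log2 2.17 ± 0.576) and Tlr7, a microglial RNA sensor (log2 -1.26 ± 0.342), each with adjusted p = 1. Among the lists 0 of 38 passed camera with the preset correlation and 0 with an estimated one. With the preset correlation 4 passed with no sex term, 5 with tissue covariates, 6 without the 4 libraries high in midbrain genes and 8 in males only. With 1 library left out there were 12 without 5xFAD replicate 4, 8 without 5xFAD replicate 3 or 5xFAD-Dp16 replicate 2, 6 without wild-type replicate 1, 2 or 4, and 2 to 4 without Dp16 replicate 2 or 4, 5xFAD replicate 1 or 2 or 5xFAD-Dp16 replicate 3 or 4. The disease-associated microglia list, which passed downward with no sex term (adjusted p = 0.0156) and without the 4 libraries (adjusted p = 0.00503), had a median of -0.0123 and the interferon response list one of 0.0173. In simulated data, without sex effects or shared tissue differences, 3.03% of genes with a 1.5-fold interaction were recovered and 73.8% with a 4-fold one. Small differences of effects were thus mostly missed even there.

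Sex was compared in the model of all libraries, where only wild-type, Dp16 and 5xFAD, which had both sexes, inform the difference. Xist, the non-coding RNA of X inactivation, was higher in females (log2 12.49 ± 0.283), and the Y-linked genes Ddx3y (log2 -11.72 ± 0.23), Uty, Eif2s3y and Kdm5d were lower. With Eif2s3x (1.53-fold) and Kdm6a (1.52-fold), X-linked genes that escape inactivation, and the Y-linked Gm29650 they made up all 8 genes called by edgeR. Over the 12 libraries of the genotypes with both sexes, edgeR called 0 genes for a sex difference of the 5xFAD effect (2448 at an unadjusted p below 0.05 against 821 expected) and DESeq2 called 0. For the Dp16 effect edgeR called 0 (169 at an unadjusted p below 0.05) and DESeq2 called 0. With camera 16 and 15 lists passed with the preset correlation, and 0 and 0 with an estimated one.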

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

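The tests of the patterns weighed here were all chosen after their results were seen, and the criteria of the tests of 1 library, of receptor dosage and of hair or skin were rewritten after their values were seen, since the first versions, which spoke for 1 library and against dosage and hair or skin, rested on too little. Within groups of 4, a library was singled out where its gap to the nearest other library exceeded Dixon's 95% critical value relative to the group's range. This happened in 6 of 172 groups for list scores and 13 of 180 for named genes, where chance gives about 1 in 20.

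The interferon response score of Dp16 replicate 4 was 0.0124 against -0.407 to -0.376 in the other Dp16 libraries (gap ratio 0.926). Without that library the list no longer passed against wild-type (adjusted p = 0.0605, in a range from 4.7e-06 to 0.0605 over the 8 libraries left out in turn), while its median moved from 0.142 to 0.117, so the share of this library cannot be decided. More microglial RNA is argued against by the homeostatic microglia median of -0.163, with scores of -0.465 ± 0.0453 in Dp16 and -0.32 ± 0.0854 in wild-type (SD). That list was not called with an estimated correlation either (adjusted p = 0.719), so this argument is weak. Dosage of the triplicated receptor genes, which may act on these genes as none of the 39 is triplicated, stays open: 1 of 4 Dp16 libraries scored above every wild-type library, and the means were -0.288 ± 0.201 and -0.48 ± 0.188 (SD, n = 4). The list was not called with an estimated correlation (adjusted p = 0.719), so the pattern itself is uncertain.

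Counts of a in the groups without the duplication came from 5xFAD replicate 4 alone (0.148 CPM against 0 in the others, gap ratio 1), while the 8 carriers averaged 2.18 ± 0.423 CPM (SD). The 4 nearest tested genes, Raly, Eif2s2, Ahcy and Itch, had a median log2 of -0.0731, which argues against spillover from a rise of these neighbours. A small share of their reads counted for a need not move their own values, so this test cannot decide that. Hair or skin in the dissections stays open. The pooled level of 16 skin, hair and pigment cell genes was 36.3 ± 3.35 CPM in carriers and 36.4 ± 4.07 in the others (ratio 0.997), but a baseline so far above the level of a would hide a small share. Krt14, a keratin of the epidermis, was at 0.0268 and 0.0689 CPM, both near the floor. Krt5, another epidermal keratin, was at 1.13 CPM in carriers and 0.989 in the others, and Tyr, a pigment cell gene, had 10 counts in 3 carrier libraries and 1 count in 1 other library. A candidate explanation is a coat colour marker carried on the engineered chromosome: 8 of 8 carriers had more counts than every other library, a result that any other cause linked to the duplication would give too. The annotated span of a overlaps Raly and Eif2s2, and the sequence of the counted reads was not analysed here.

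Other libraries stood apart as follows. The adult neurogenesis score was 0.671 in 5xFAD replicate 1 and 0.0773 to 0.124 in the other 5xFAD libraries (gap ratio 0.921). Wild-type replicate 4 had a CA1 score of -1.02 against 0.171 to 0.377 (0.853) and a midbrain and hypothalamus score of 3.00 against -1.29 to -0.776 (0.88). 5xFAD replicate 4 had a ribosomal protein score of 0.733 against 0.00917 to 0.117 (0.851), a clustered protocadherin score of -0.217 against -0.0517 to -0.0397 (0.932) and App at 1640 CPM against 1870 to 1900 (0.891). In Dp16, Gart was 50.7 CPM in replicate 1 against 49.1 to 49.4 (0.847) and Bach1 21.4 against 17.4 to 17.8 (0.892). In Dp16 replicate 2, Ifngr2 was 110 CPM against 104 to 105 (0.903), Pik3r3 29.6 against 28.6 to 28.7 (0.865) and Ccl6 0.942 against 1.63 to 1.68 (0.939). Gpr84 was 0.692 CPM in Dp16 replicate 4 against 0.112 to 0.188 (0.869). In wild-type, Il10rb was 5.60 CPM in replicate 1 against 8.34 to 8.64 (0.9) and Cd22 0.536 against 0.0445 to 0.0873 (0.913). Ctse was 0.0436 CPM in wild-type replicate 2 against 0 (gap ratio 1), and Frem3 4.39 in wild-type replicate 4 against 1.83 to 2.18 (0.864). In 5xFAD-Dp16, Ccl6 was 10.6 CPM in replicate 4 against 12.8 to 13.1 (0.888), and the total was 25 M counts in replicate 2 against 17.8 to 18.9 (0.847).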

How the results depend on the processing

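The settings of leaving out 4 libraries and of tissue scores as covariates, and the tests on them, were chosen after the data were seen; the other settings were planned. For the named genes in their comparisons no fitted direction that had been called turned under the settings run. DESeq2 ended no such call, but 70 ended in males only, 60 in models of 2 groups, 16 with the replicate block, 15 with each limma setting, 14 without the 4 libraries and 2 to 6 with the other normalization, filters, no sex term or tissue covariates. Of 140 calls of named genes in the 5 comparisons of genotypes, 51 ended when at least 1 single library was left out. Where a count below moved, the cause was not tested unless the setting itself uses fewer samples or genes.

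In the order Dp16 against wild-type, 5xFAD against wild-type, 5xFAD-Dp16 against wild-type, 5xFAD-Dp16 against 5xFAD and 5xFAD-Dp16 against Dp16, the counts of called genes were 14, 162, 169, 9 and 141. They were 38, 292, 267, 27 and 269 with DESeq2, 210, 398, 355, 75 and 620 with no low-count filter (157, 70, 26, 24 and 75 of them lower), 0, 44, 61, 0 and 49 in males only by edgeR (400 and 1236 genes at an unadjusted p below 0.05 beside the counts of 0), and 4, 76, 40, 0 and 81 in models of 2 groups (760 beside the 0). Without a low-count filter edgeR also called 128 genes for the interaction, 404 for sex, and 872 and 95 for sex differences of the 5xFAD and Dp16 effects, and the correlation of effects on both backgrounds was 0.246 for 5xFAD and, reversed, -0.23 for Dp16. DESeq2 called 21 genes for sex and gave 0.89 for the Dp16 correlation. limma on log2(RPKM + 0.1) and on log2(RPKM + 1) each called 9 genes in Dp16 against wild-type, and the latter gave medians of the segment of 0.395 and, in 5xFAD-Dp16 against 5xFAD, 0.461. Leaving out the 4 libraries gave 39 genes in Dp16 against wild-type. The tissue covariates gave 34 there, 32 in 5xFAD-Dp16 against 5xFAD and 0.742 for the Dp16 correlation. No sex term gave 17 genes in 5xFAD-Dp16 against 5xFAD.

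Called lists numbered 16, 17, 15, 6 and 19 in the same order and 0 for the interaction. With an estimated correlation they were 0, 6, 7, 0 and 6. For Dp16 against wild-type they were 6 in males only and 9 without the 4 libraries. For 5xFAD-Dp16 against 5xFAD they were 12 with no sex term and 10 with tissue covariates. For the interaction they were 4 with no sex term, 8 in males only, 6 without the 4 libraries, 5 with tissue covariates and 1 with either limma setting.

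Leaving out each library in turn gave 3 to 17 genes in Dp16 against wild-type (5 without wild-type replicate 1 or Dp16 replicate 1 or 2, 3 without wild-type replicate 2 or Dp16 replicate 3, 9 without wild-type replicate 3 or 5xFAD-Dp16 replicate 1 or 4, 8 without Dp16 replicate 4), 109 to 189 in 5xFAD against wild-type, 80 to 172 in 5xFAD-Dp16 against wild-type (80 and 99 without wild-type replicates 1 and 3), 0 to 11 in 5xFAD-Dp16 against 5xFAD (0 by edgeR without Dp16 replicate 1, 2 or 3, 5xFAD-Dp16 replicate 1, 2 or 4 or 5xFAD replicate 3, with 452 to 805 genes at an unadjusted p below 0.05; 5 and 4 without wild-type replicates 1 and 2, 4 and 3 without 5xFAD replicates 1 and 4) and 76 to 146 in 5xFAD-Dp16 against Dp16 (76 and 80 without Dp16 replicates 2 and 3). It gave 0 to 0 for the interaction, 6 to 9 for sex, and 0 to 1 and 0 to 2 for the sex differences of the 5xFAD effect (1 without wild-type replicate 2 or 5xFAD replicate 1) and the Dp16 effect (2 without wild-type replicate 2). The correlations ranged from 0.604 to 0.887 for 5xFAD and from 0.966 (without wild-type replicate 4) to 1 for Dp16, and the segment's medians from 0.452 (without wild-type replicate 1) to 0.582 and from 0.534 to 0.583. The Dp16 correlation of the main fit covers 15 genes and is carried by a, at log2 8.39 and 5.4 far from the others. It therefore says little about agreement among the segment's genes. Lists ranged from 7 to 16 (7 without wild-type replicate 4, 10 without wild-type replicate 1), 12 to 25, 11 to 20, 3 to 10 (3 without wild-type replicate 1, 10 without 5xFAD-Dp16 replicate 1 or 5xFAD replicate 2), 18 to 22 and, for the interaction, 0 to 12 (12 without 5xFAD replicate 4, 8 without 5xFAD-Dp16 replicate 2 or 5xFAD replicate 3, 6 without wild-type replicate 1, 2 or 4, 4 without 5xFAD-Dp16 replicate 3, 3 without Dp16 replicate 4, 5xFAD-Dp16 replicate 4 or 5xFAD replicate 1, 2 without Dp16 replicate 2 or 5xFAD replicate 2).

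The replicate numbers do not pair the samples: the correlations of deviations ranged from -0.354 to 0.354 over 24 pairs with the same number, 9 of them above 0.1, and 3 of 16 samples correlated best with their own number. With the replicate block edgeR called 0 genes in 5xFAD-Dp16 against 5xFAD (712 at an unadjusted p below 0.05) and 2 lists passed for the interaction; in the other comparisons the counts were 19, 162, 173 and 148. Depth was not varied, so its share in the low simulated recovery of 1.5-fold changes was not tested. The low-count filter, which depends on depth, left 16684 of 30883 genes.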

Other observations

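The tests reported here on Thy1 and on other splits of the samples were chosen after the results were seen, and for effects on both backgrounds the statistic of the splits was set to the number of shared genes after the correlations had been seen. Beyond the rises, some genes were lower in mice with the duplication, chosen here after their values were seen. Cbs was at 31.2 ± 4.35 CPM in wild-type, 18.9 ± 3.49 in Dp16, 26.0 ± 1.08 in 5xFAD and 19.7 ± 3.15 in 5xFAD-Dp16 (SD, n = 4). It passed with edgeR in 5xFAD-Dp16 against wild-type, a call that ended without 12 of the 16 libraries left out in turn, and did not pass in Dp16 against wild-type (log2 -0.73, edgeR adjusted p = 0.0912), where it passed with DESeq2 and without the 4 libraries high in midbrain genes. Pik3r3 was at 39.0 ± 4.03, 28.9 ± 0.497, 38.2 ± 3.37 and 26.4 ± 2.59 CPM in the same order. Its values against the matching group without the duplication were log2 -0.43 (edgeR adjusted p = 0.197) and -0.49 (adjusted p = 0.195), and both passed with DESeq2. Slc5a5, a sodium and iodide transporter also chosen after its values were seen, went the other way. It was at log2 0.62 in 5xFAD-Dp16 against 5xFAD (edgeR adjusted p = 0.247) and passed with DESeq2 and in both settings for tissue content.

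Klf15 fell in 5xFAD-Dp16 against Dp16, from 25 ± 1.26 to 16.6 ± 0.669 CPM, and was at 23.4 ± 1.94 in wild-type and 22.5 ± 3.09 in 5xFAD. Its call ended without Dp16 replicate 2 or 3 or 5xFAD-Dp16 replicate 1, 2 or 4 (adjusted p up to 0.153). In the same comparison Hif3a (log2 -1.51) and Dio2 (log2 -0.65), a thyroid hormone deiodinase, were chosen after their values were seen. Each had an edgeR adjusted p = 0.0515 and passed with DESeq2. Cholesterol synthesis genes were higher in 19 of 19 in 5xFAD-Dp16 against wild-type (median log2 0.321, adjusted p = 1.54e-11, and adjusted p = 0.0525 with an estimated correlation), with 8 passing when adjusted over the list alone. Oligodendrocyte genes were higher in 18 of 18 in the same comparison (median log2 0.363, adjusted p = 2.71e-10, and adjusted p = 0.201 with an estimated correlation), with a median of 0.197 without 5xFAD-Dp16 replicate 3 (adjusted p = 5.1e-06), whose midbrain and hypothalamus score was 3.12. Among orthologues of Alzheimer disease risk genes, 4 of 25 rose in that comparison, namely Trem2, Plcg2, Spi1 and Abi3 (adjusted p = 0.0525 with an estimated correlation), and 5 passed when adjusted over the list alone. The call of Plcg2 ended without wild-type replicate 1 (adjusted p = 0.053), that of Spi1 without wild-type replicate 1, 2 or 3 or 5xFAD-Dp16 replicate 1, 2 or 4 (up to 0.137) and that of Abi3 without wild-type replicate 1 or 2 or 5xFAD-Dp16 replicate 1, 2 or 4 (up to 0.105).

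Thy1 was higher in all 8 5xFAD carriers than in every other library. More neuronal RNA is argued against by the presynaptic median of -0.177, and spillover from neighbours by the median of -0.18 over the 4 nearest tested genes. A candidate explanation is reads from Thy1 sequence within the transgenes, for which 8 of 8 carriers were above every other library. Higher expression of the mouse gene itself would give the same result and stays open.

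Other splits of the samples into groups of the same sizes were counted, the real one included. The real split called the most genes in Dp16 against wild-type (1 of 35 splits gave as many, 14 genes, highest other 1) and 5xFAD-Dp16 against wild-type (1 of 35, 169, highest other 0). It also did in 5xFAD-Dp16 against 5xFAD (1 of 35, 9, highest other 1) and 5xFAD-Dp16 against Dp16 (1 of 35, 141, highest other 0). For sex 2 of 60 splits gave as many (8, highest other 21). With 35 splits no share below 1 of 35 is possible, and these tests were not adjusted for their number. Chance is thus made less likely here but is not excluded. The segment's medians were also largest in the real split (1 of 35 each, 0.521 and 0.537, highest others 0.369 and 0.34). The numbers of shared genes of the effects on both backgrounds were too (1 of 60 each, 100 and 8 genes, highest other 0). That 0 was nearly fixed, since a split with 0 genes in either comparison can share none. Other splits of 5xFAD-Dp16 against Dp16 called 0, and those of 5xFAD-Dp16 against 5xFAD at most 1. In 5xFAD against wild-type 2 of 35 splits gave as many as the real 162 genes, so by this count chance cannot be excluded. The splits do not settle this for the 100 of them shared with 5xFAD-Dp16 against Dp16 either, since that comparison nearly fixed the shared count. Other values argue against chance for those 100. Independent lists would share 1.33, and the groups share no library, though 1 fit gave both. Scores of the preset disease-associated microglia list were 0.691 to 1.25 in 5xFAD and -1.05 to -0.734 in wild-type. They were 0.577 to 0.86 in 5xFAD-Dp16 and -1.03 to -0.679 in Dp16. For the rest of the 162 genes chance stays open. Besides the real one, the split that reached 162 in 5xFAD against wild-type called 1024 genes. It set wild-type replicate 4 and 5xFAD replicates 2, 3 and 4 against the rest. That places all 3 libraries of the comparison with high midbrain scores on 1 side. Other splits that did so called 0 or 1 genes, so this placement alone does not account for the 1024. For the interaction the splits decide nothing, since a count of 0 genes by edgeR (332 at an unadjusted p below 0.05, DESeq2 0) is reached by 60 of 60 splits by construction (highest other 32).

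For counts of lists passing camera with the preset correlation chance cannot be excluded in the 5 comparisons of genotypes. As many lists passed in 9 of 35 splits for Dp16 against wild-type (16, highest other 19), 16 of 35 for 5xFAD against wild-type (17, highest other 25) and 17 of 35 for 5xFAD-Dp16 against wild-type (15, highest other 24). The same held in 34 of 35 for 5xFAD-Dp16 against 5xFAD (6, highest other 22) and 7 of 35 for 5xFAD-Dp16 against Dp16 (19, highest other 24). For the interaction, with 0 lists, 60 of 60 splits give as many by construction (highest other 22), which decides nothing.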
